A study of Homo sapiens and Monodelphis domestica and Dasypus novemcinctus with 4 samples.

How the data were processed

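RNA-seq libraries of 4 samples were analysed, with 1 library in each of 4 groups: differentiated human endometrial stromal cells, undifferentiated human endometrial stromal cells, mid-stage pregnant armadillo endometrium and pregnant opossum endometrium. Groups were taken from the sample titles. Total RNA was extracted with a column kit and DNase, and mRNA libraries were read at 75 bp, per the labels' protocols. The build GRCh37 is named in the submitters' processing notes for the human and armadillo samples. The aligner, the counting program, the annotation release and the opossum build are not given in the sources used here.

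The armadillo and opossum tables hold read counts per Ensembl gene, per the file headers. The armadillo table lists only genes with at least 1 read, and its last line repeats the total of 13218476 and was left out. The opossum table lists 21614 genes, 16456 of them above 0. The human table, as deposited, holds a signal per gene that is not a read count. Between 77.3% and 78.5% of its non-zero values were whole multiples of 74, and its columns summed to 1207267583 or more, so the values were read as aligned length and divided by 74 to give read equivalents. The opossum table also has a column that the authors headed RPKM, but its values are a coverage in reads per base. Rounding of that column to 5 decimals leaves the length, reads divided by the value, uncertain by under 0.1 bases for 9949 genes. For 100% of these the length lay within 0.1 of a whole number of bases, against 20% for lengths spread evenly, with no division by the library total. The opossum analyses therefore used the counts, and reads per base entered only as an alternative. No per-sample column was left unmapped.

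Depth was 16314426.8 and 16719890.2 read equivalents for the runs of the differentiated sample, 16946257.2 and 18022393.9 for those of the undifferentiated sample, 13218476 reads for armadillo and 20099950 for opossum. The sources used here do not say what the 2 columns of each human sample are. They were taken as runs of 1 library and counted as 1 replicate, and the pooled values and their intervals rest on that. On placed autosomal genes the runs had a Pearson r of 0.999 on log2 values in both conditions. The mean chi-square per gene between runs, over genes with at least 20 read equivalents, was 1.07 for the differentiated and 2.01 for the undifferentiated runs, where sampling noise alone gives about 1. In the second differentiated run the values on the X chromosome did not follow those of the first run (r -0.0297). Genes on X and genes with no chromosome in the annotation used (2434 in all, HOXA10 among them) were therefore taken from the first run of each condition, and the other 19003 genes from the mean of both runs. Genes of the Y chromosome and transcripts of X inactivation were not used here.

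Values were divided by the library total and expressed as CPM, counts or read equivalents per 1000000. Human ratios are log2 of differentiated over undifferentiated values with a pseudocount of 1 CPM, which understates differences of low genes. Plain ratios are given without the pseudocount. Genes entered when the larger value was at least 10 CPM. Human read equivalents were rounded to whole numbers for 95% intervals of a ratio, exact and conditional on the sum of both values (Clopper-Pearson). A value of 0 was treated as a floor of 3 read equivalents, which over both runs is 0.0908 CPM in the differentiated and 0.0858 in the undifferentiated sample. Intervals and floors cover counting error only. With 1 library per group no test was made and no p-value was computed.

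Before the data were examined, 26 gene lists with 518 entries, the settings and the rule for named genes were fixed. The lists cover decidual markers, steroid-receptor targets, cyclic AMP response, cell cycle, extracellular matrix, proteases and inhibitors, contractile genes, cytokines and chemokines, immune tolerance, interferon response, steroid receptors and enzymes, endometrial transcription factors, the insulin-like growth factor axis, WNT and BMP signalling, prostaglandins, angiogenesis, oxidative and endoplasmic reticulum stress, sterol synthesis and ribosomal proteins. They also cover stromal, epithelial and gland, endothelial, leukocyte, smooth muscle, trophoblast and yolk sac, and erythroid markers. Named human genes are the 10 highest and 10 lowest log2 ratios, 8 genes named in advance (PRL, IGFBP1, FOXO1, PGR, HOXA10, HOXA11, HAND2 and CEBPB) and up to 4 members of each list with the largest absolute log2 ratio. Further list members given as examples (ETS1, ADAMTS1, TIMP3, ADAMTS5, TOP2A, MKI67, FN1, THBS1, BMP2 and SST in opossum, and AFP, APOA2, GCM1, CYP19A1, PAPPA2, AURKA, KIF11, BIRC5, KRT7, KRT18, WFDC2, FOS, DUSP1 and JUNB among them) were chosen after their values were seen, unless the rule also names them. Some genes that meet the rule are not reported here. Across species they are the 10 genes with the highest smaller value of differentiated human and armadillo among those below 2 CPM in opossum, the 10 highest in opossum among those below 2 in the others, the 10 most abundant genes of each library, and up to 4 members of each list with the highest value in any library.

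For each list with at least 5 members entering, the median log2 ratio was set among the medians of 10000 random lists of the same size, in which each member was replaced by one of 100 neighbours in mean expression. A list was called outside when its percentile was above 97.5 or below 2.5, as a description of these libraries. Gene names of the armadillo and opossum tables were matched to names of the human table, brought to current symbols by Ensembl ID (19812 of 21497 human IDs had one). Names held by more than 1 gene of a table were left out, which gave 8311 genes in all 3 tables. Since the armadillo table lists only genes with reads, matched genes were selected on having an armadillo read. Named genes held 87.8% of armadillo reads and 72.8% of opossum reads. The threshold of 2 CPM corresponds to 40.2 reads in opossum and 26.4 in armadillo. GENCODE 29 served only to tell which chromosome a human gene lies on, and no coordinates are given since its build differs from the one in the processing notes.

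The alternatives were median-of-ratios scaling, upper-quartile scaling, totals without the 20 most abundant genes, pseudocounts of 0.1 and 5, no minimum or a minimum of 50, a 2-fold threshold, the mean of a list, thresholds of 1 and 5 CPM, at least 5 with below 1, rescaling over matched genes, the undifferentiated library in place of the differentiated, and correlations over detected genes. The first run alone, no X or unplaced genes, both run pairs, interval bounds on human read equivalents, counting limits in opossum and opossum reads per base were chosen after seeing the data. The ratio and list steps were tested on simulated data drawn from the 21437 human genes used. There 50 of 50 genes raised 8-fold and 50 of 50 lowered 8-fold passed the 4-fold threshold, 0 of 100 genes changed 2-fold and no unchanged gene did, and 91 of 100 unchanged lists lay inside the central 95%. Changed genes were drawn from those at 20 CPM or more, and only counting noise was simulated. The simulation therefore checks the steps and does not give the rate of false calls in the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.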

Results

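RNA-seq was available for 4 libraries of endometrium, the lining of the uterus, with 1 library in each group. Cultured human endometrial stromal cells, the connective tissue cells of that lining, were sequenced in a differentiated and in an undifferentiated condition. The differentiation of these cells into decidual cells is called decidualization. The other libraries came from mid-stage pregnant endometrium of the armadillo and from pregnant endometrium of the opossum, a marsupial. The human table held 2 columns per condition, taken here as runs of 1 sample, of 16314426.8 and 16719890.2 read equivalents for the differentiated cells and of 16946257.2 and 18022393.9 for the undifferentiated cells. The armadillo library held 13218476 reads and the opossum library 20099950 reads. Values are given as CPM, counts or human read equivalents per 1000000 of the library total. With 1 library per group there was no replicate error, so no difference was tested, and intervals give counting error only.

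The first comparison asked which genes differed between differentiated and undifferentiated human stromal cells. SST, ADH1B and CRISPLD2 had the highest log2 ratios of the differentiated over the undifferentiated library, and the metalloproteinase genes MMP10, MMP1 and MMP3 the lowest. SST (ENSG00000157005), which encodes the peptide hormone somatostatin, stood at 420.3 CPM in differentiated and 0.201 in undifferentiated cells, a ratio of 2089 (95% counting interval 1019 to 5224). PRL (ENSG00000172179), the prolactin gene, was 21.5-fold higher (13.3 to 37.5), at 10.5 against 0.489 CPM. MMP10 (ENSG00000166670) was 1213-fold lower (699 to 2364), at 0.366 against 443 CPM. Of 9369 genes entering, 212 were at least 4-fold higher and 212 at least 4-fold lower in the differentiated library.

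The highest log2 ratios, on values with a pseudocount of 1 CPM, belonged to SST (8.45), ADH1B (7.67), CRISPLD2 (7.35), IGF1 (6.95) and SFRP1 (6.09). They were followed by ADRA2C (5.68), MASP1 (5.39), RASL11B (5.37), C7 (5.28) and IGFBP3 (5.10). ADH1B, an alcohol dehydrogenase, rested on 3 read equivalents in the undifferentiated runs, and its ratio was 2546 with a counting interval of 881 to 12488. CRISPLD2, a secreted protein gene, stood at 1889 against 10.6 CPM, a ratio of 179 (161 to 198). The lowest log2 ratios were those of the metalloproteinase genes MMP10 (-8.35), MMP1 (-7.86), MMP3 (-7.23) and MMP11 (-6.40), and of F2RL1 (-6.63) and CNIH3 (-6.38). ITGA2 (-5.96), NTM (-5.84), CCN3 (-5.54) and SYT7 (-5.47) completed that group. MMP1, interstitial collagenase, stood at 14.9 against 3683 CPM, 248-fold lower in the differentiated library (227 to 271). ITGA2, an integrin subunit that binds collagen, stood at 20.5 against 1332 CPM, 65.0-fold lower (60.4 to 70.4).

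**Figure D1:**
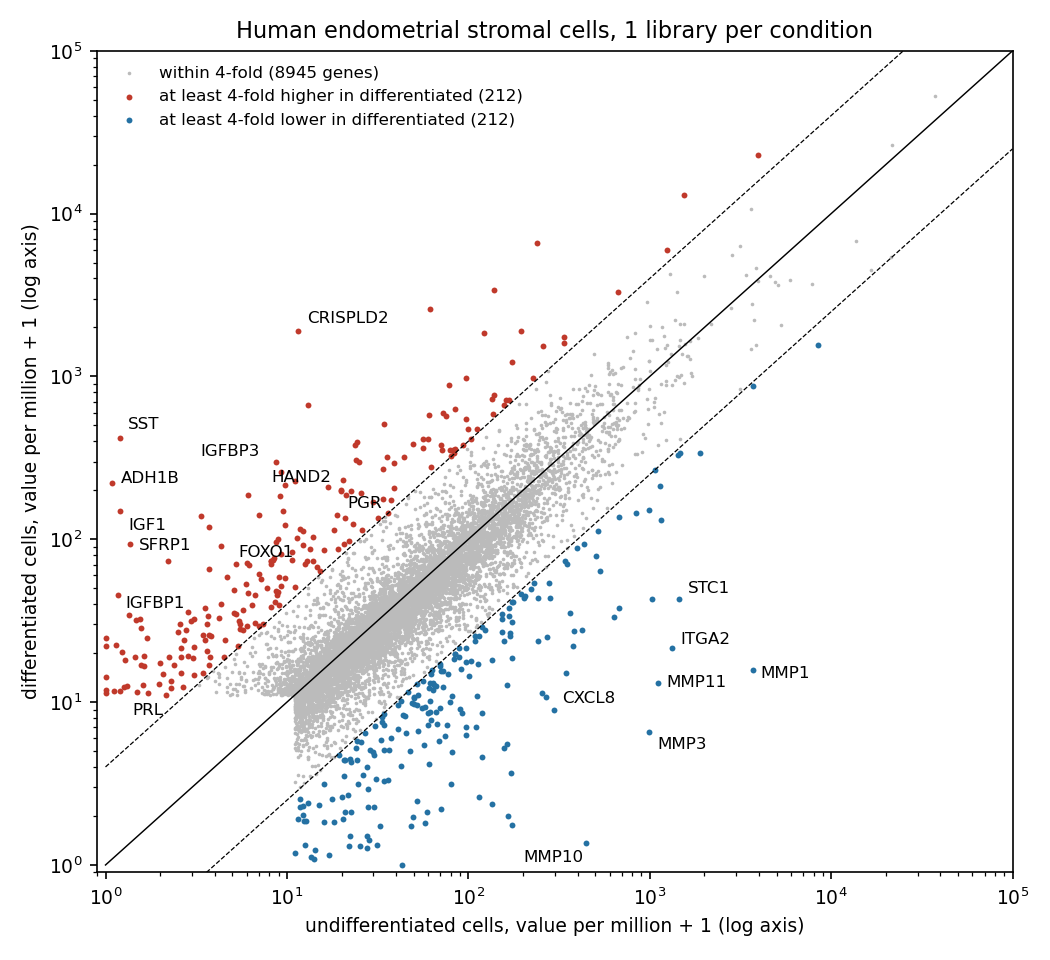
Values of 9369 genes in undifferentiated (horizontal, log axis) and differentiated (vertical, log axis) human endometrial stromal cells, in read equivalents CPM with 1 added, 1 library per condition. The solid line marks equal values and the dashed lines 4-fold differences; the 212 red genes lie at least 4-fold higher and the 212 blue genes at least 4-fold lower in the differentiated library.

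Markers of decidual cells were mostly higher in the differentiated library. Of 17 members entering, 9 were at least 2-fold higher, 4 at least 2-fold lower and 4 neither, and the median log2 ratio was 1.67. IGFBP1, a secreted binding protein of insulin-like growth factors, was 12.1-fold higher (9.84 to 15.2), at 32.7 against 2.69 CPM. FOXO1, a transcription factor of decidual cells, was 5.57-fold higher (5.03 to 6.17), and DKK1, a secreted WNT antagonist, was 8.42-fold higher (8.07 to 8.78). The members on the lower side were STC1, DIO2, IL11 and BMP2. STC1, the stanniocalcin gene, stood at 41.7 against 1454 CPM, 34.8-fold lower (33.0 to 36.8), and DIO2, a deiodinase, was 64.5-fold lower (38.0 to 118). CEBPB, a transcription factor, was 1.68-fold lower (1.59 to 1.77), with a log2 ratio of -0.74.

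Genes known to respond to glucocorticoid or progesterone receptors stood higher as a group. Of 14 entering, 12 were at least 2-fold higher and none was at least 2-fold lower, with a median log2 ratio of 2.31. ZBTB16, a zinc finger repressor, stood at 23.9 CPM and had no read equivalent in undifferentiated cells, so it was at least 278-fold higher against a floor of 3 over both runs. With ZBTB16 at that bound, the median of the list was still 2.31. CEBPD was 15.6-fold higher (13.0 to 18.8) and HSD11B1, which regenerates cortisol from cortisone, was 9.85-fold higher (8.86 to 10.9). Among steroid receptors and enzymes, 5 of 10 members were at least 2-fold higher and 1 at least 2-fold lower, with a median of 1.13, or 0.20 with no minimum on the values. The progesterone receptor gene PGR was 3.47-fold higher (3.26 to 3.68), at 137 against 39.5 CPM. STAR, which moves cholesterol into mitochondria, was 24.8-fold higher (16.3 to 40.1), and the steroid sulfatase gene STS 4.81-fold higher (4.41 to 5.25).

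Transcription factors of the endometrium followed the same direction, with 14 of 28 at least 2-fold higher, 1 at least 2-fold lower and a median of 0.99. HAND2 was 9.23-fold higher (8.56 to 9.97), HOXA10 3.91-fold higher (3.55 to 4.31), HOXA11 3.68-fold higher (3.48 to 3.90) and MEIS1 4.12-fold higher (3.95 to 4.29). ETS1 was the member on the lower side, with a log2 ratio of -1.81. In the insulin-like growth factor axis, 7 of 14 members were at least 2-fold higher and none was at least 2-fold lower, with a median of 1.12. IGF1 stood at 147 against 0.203 CPM (ratio 726, 357 to 1833). IGFBP3 was 38.7-fold higher (34.3 to 43.8) and IGFBP4, at 12949 against 1549 CPM, 8.36-fold higher (8.28 to 8.43). Of 18 genes that respond to cyclic AMP, 8 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 0.83. The phosphodiesterase genes PDE4D and PDE7B were 10.6-fold (9.53 to 11.8) and 6.99-fold (6.30 to 7.73) higher, while ATF3 was 8.61-fold lower (6.29 to 12.1).

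Matrix protease, proliferation and sterol genes stood lower. Of 19 proteases and inhibitors entering, 8 were at least 2-fold lower and 3 at least 2-fold higher, with a median of -0.61 (-0.37 with no minimum) and a mean of -1.53. The members on the higher side were ADAMTS1 (log2 ratio 4.77), the inhibitor gene TIMP3 (2.87) and ADAMTS5 (2.26), and MMP14 was at -2.43. Cell cycle genes had a median of -0.73, with 7 of 29 at least 2-fold lower (4 with upper-quartile scaling) and none at least 2-fold higher. The lowest of them were subunits of the replicative helicase, MCM5 at 4.26-fold lower (3.77 to 4.82), MCM4 at 3.47-fold lower (3.22 to 3.74) and MCM7 at 2.74-fold lower (2.57 to 2.93). TOP2A was at 0.06 and MKI67 at -0.76. Cholesterol and fatty acid synthesis genes had a median of -1.04, with 9 of 18 at least 2-fold lower and none at least 2-fold higher. STARD4 was 5.61-fold lower (4.95 to 6.38), INSIG1 4.28-fold lower (4.05 to 4.53) and SQLE, an epoxidase of sterol synthesis, 2.76-fold lower (2.57 to 2.97).

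Other lists held members on both sides. Of 13 cytokine and chemokine genes, 6 were at least 2-fold higher and 5 at least 2-fold lower. CXCL12, at 1842 against 121 CPM, was 15.2-fold higher (14.7 to 15.7), IL1R1 was 15.4-fold higher (14.5 to 16.3) and CCL2 12.4-fold higher (10.9 to 14.1). CXCL8, the interleukin 8 gene, was 37.0-fold lower (32.8 to 42.0). The median of this list was 0.78 and its mean 0.20, and with no minimum on the values the median was -0.08. Angiogenesis genes had a median of -0.69 and a mean of -0.13, with 4 of 16 at least 2-fold higher and 4 at least 2-fold lower. ANGPT1 was 12.5-fold higher (11.6 to 13.4) and MET, the receptor of hepatocyte growth factor, 6.88-fold lower (5.93 to 8.05). Of 26 extracellular matrix genes, 8 were at least 2-fold higher and 5 at least 2-fold lower, with a median of 0.34. COL3A1 (22919 against 3937 CPM) and FBLN1 were 5.82-fold (5.79 to 5.85) and 10.1-fold (9.80 to 10.5) higher, while FN1, the fibronectin gene, was at -1.97 and THBS1 at -1.88.

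Of 22 WNT and BMP signalling genes, 3 were at least 2-fold higher and 7 at least 2-fold lower, with a median of -0.33, which was 0.07 with no minimum on the values. SFRP1, a secreted WNT antagonist, had a ratio of 248 (146 to 469), whereas INHBA was 8.85-fold lower (8.58 to 9.14). Genes of immune tolerance had a median of 0.78, with 2 of 11 at least 2-fold higher (4 with upper-quartile scaling), HLA-E (2.40-fold, 2.31 to 2.49) and CD55 (2.36-fold, 2.24 to 2.48), and 1 at least 2-fold lower, PDCD1LG2 (2.499-fold, 2.27 to 2.77). Interferon-response genes had a median of -0.08 and a mean of 0.37, with 4 of 12 at least 2-fold higher and 2 at least 2-fold lower, and with no minimum the median was 0.21. IFI44L was at least 248-fold higher against the floor of 3 read equivalents over both runs, and IRF1 was 4.44-fold lower (3.99 to 4.95). With IFI44L at its bound the median was still -0.08. In the prostaglandin pathway the median was -0.30 (0.05 with no minimum) and the mean 0.07, with 2 of 9 at least 2-fold higher, among them the receptor gene PTGER2 at 5.71-fold (4.803 to 6.75), and AKR1B1 3.56-fold lower (3.38 to 3.74).

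Contractile genes had a median of 0.42 and a mean of 0.84, with 4 of 13 at least 2-fold higher and none at least 2-fold lower. ACTA2, smooth muscle actin, was 7.57-fold higher (7.28 to 7.87) and ACTG2 54.4-fold higher (25.9 to 135). Oxidative and endoplasmic reticulum stress genes had a median of -0.17, with 3 of 22 at least 2-fold higher, TXN the highest of them at 3.05-fold (2.95 to 3.16), and 2 at least 2-fold lower, DDIT3 and HMOX1. All 21 ribosomal protein genes entering lay within 2-fold when scaled by the total (2 were above it with upper-quartile scaling), with a median of 0.58 and RPLP0 the highest at 1.98-fold (1.93 to 2.02).

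Markers of cell types were measured in the same libraries. Of 14 stromal markers, all entered, 3 were at least 2-fold higher and 3 at least 2-fold lower, and the median was 0.53. VIM, the vimentin gene, was 2.56-fold lower (2.54 to 2.58) and PDGFRB 2.45-fold lower (2.43 to 2.48). Of 20 epithelial and gland markers, 6 entered, with a median of -0.98, or -0.02 with no minimum. KRT19 was 3.75-fold lower (3.45 to 4.06) and MUC1 5.18-fold higher (4.05 to 6.68), at 11.7 CPM. Smooth muscle markers had a median of 0.50 and a mean of 1.22, with 3 of 7 at least 2-fold higher, ACTG2, ACTA2 and LMOD1, all of which are also in the contractile list. For the endothelial list 1 marker entered, TEK at 16.0 against 40.6 CPM, and for the leukocyte list 1 entered, CD68 at 224 against 129. Among trophoblast and yolk sac markers, PSG1 was 34.6-fold higher (23.2 to 54.7), at 23.9 CPM, and TFAP2C was at -0.40. No erythroid marker reached 10 CPM.

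Against 10000 random lists of the same size and expression, 10 of the 22 lists with at least 5 members had a median above the central 95% and 5 below it. Decidual markers, steroid-receptor targets, transcription factors and the insulin-like growth factor axis were at percentile 100, and cell cycle and sterol synthesis at percentile 0. Cyclic AMP response and steroid receptors and enzymes were at 99.99, cytokines at 99.96, immune tolerance at 99.8, ribosomal proteins at 99.8 and stromal markers at 97.85. Some of these lists share members, such as HAND2 and CEBPD in steroid-receptor targets and transcription factors, and HSD11B1 in both steroid lists. Their percentiles are therefore not independent. Angiogenesis was at 0.01, proteases at 0.15 and epithelial markers at 2.1. Extracellular matrix (96.4), smooth muscle (96.3), contractile (94.4), interferon (56.1), stress (29.9), prostaglandin (22.3) and WNT and BMP genes (7.65) lay inside it. By the mean in place of the median, cytokines, immune tolerance, angiogenesis, stromal and epithelial markers lay inside the central 95%, and contractile and smooth muscle genes above it.

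**Figure D2:**
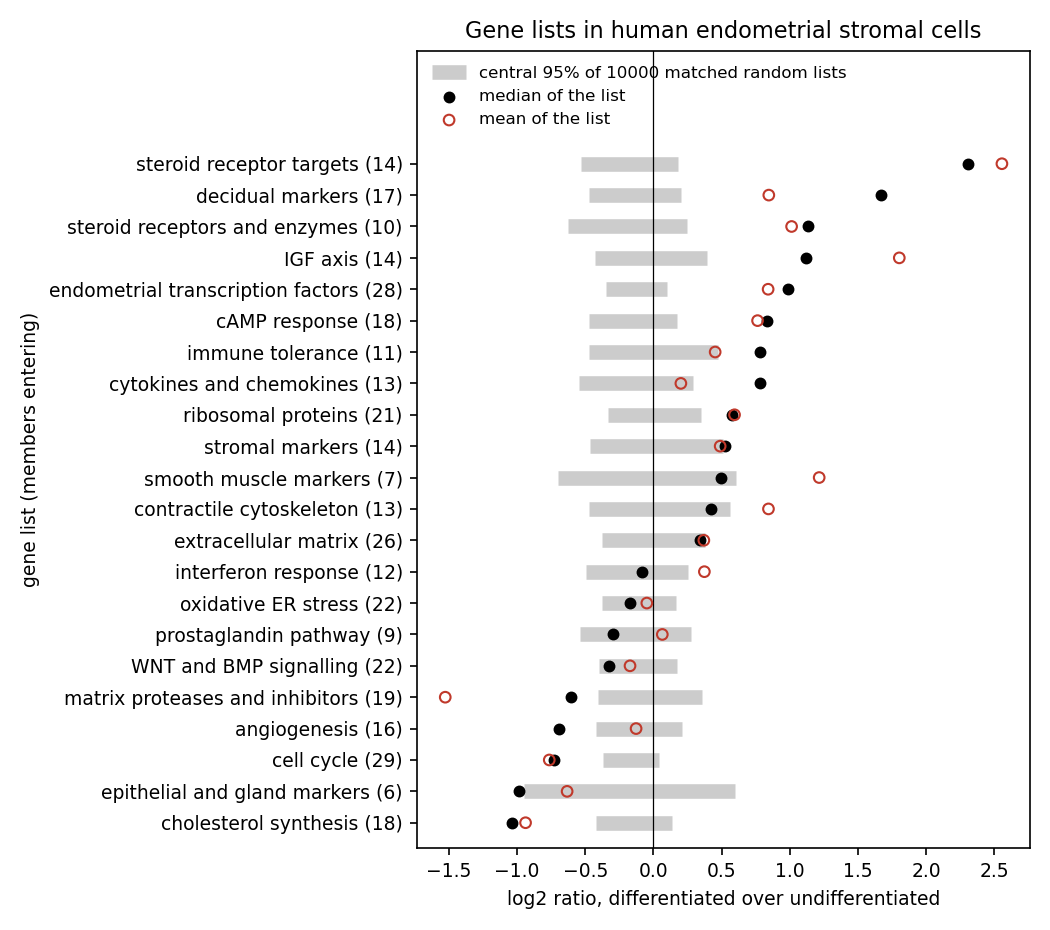
Median (black) and mean (open red) log2 ratio of differentiated over undifferentiated human cells for 22 gene lists, with the number of members entering in brackets. Grey bars span the central 95% of medians of 10000 random lists matched on expression; steroid-receptor targets have the highest median (2.31) and sterol synthesis the lowest (-1.04).

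The median log2 ratio of all genes entering was -0.14. Median-of-ratios scaling moved each ratio by 0.10 and upper-quartile scaling by 0.17, and under both the sign of the interferon median turned positive (0.02 and 0.24) while no other list median changed sign.

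The second comparison asked which genes were detected in differentiated human cells and in armadillo but not in opossum, and the reverse. Over 8311 genes matched by symbol, 599 were at or above 2 CPM in differentiated human cells and armadillo and below 2 in opossum. These made up 9.87% of the 6069 genes above that level in both eutherian libraries. LTBP2, a matrix protein that resembles binding proteins of TGF-beta, stood at 877 and 630 CPM in human and armadillo against 1.34 in opossum. In the reverse direction, 256 genes were at or above 2 in opossum and below 2 in both others, and ESM1 led them at 6733 CPM against 1.97 in armadillo and 0 in differentiated human cells. Genes with no armadillo read are absent from that table and could not enter the 256, whereas genes with no opossum read could enter the 599. The counts 599 and 256 are therefore not directly comparable. A further 5470 genes were at or above 2 in all 3 libraries.

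ATP2B4 stood at 600 and 301 CPM in human and armadillo against 1.89 in opossum, TM4SF1 at 572 and 291 against 0.945, and MATN2 at 187 and 643 against 0.896. AP2B1, an adaptor subunit of clathrin coats, stood at 316 and 250 and had 0 opossum reads, with a 95% counting limit of 0.184 CPM. That limit covers counting error only, and reads lost through the opossum gene model would escape it. YWHAQ, FAT4, HSPB6 and MAP1B had 5, 1, 3 and 18 opossum reads. Among members of the fixed lists, DKK1 was at 599 and 75.5 CPM against 0.199, and RGS2 at 175 and 45.2 against 1.79. BMP2, SST and HAND2 stood at 42.9, 420 and 198 CPM in differentiated human cells, at 76.3, 8.78 and 3.63 in armadillo and at 0.498, 0 and 0.896 in opossum. HAND2 in armadillo thus lay close to the threshold of 2. For ATP2B4 and RGS2 the 95% counting limit of the opossum value reached 2.59 and 2.48 CPM, above the threshold.

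The 10 genes highest in opossum among those below 2 CPM in the other libraries included APOA1, an apolipoprotein gene of the trophoblast and yolk sac list. TC2N stood at 5670 CPM, the hepatic lipase gene LIPC at 3095, PCK1, an enzyme of gluconeogenesis, at 1388 and APOA1 at 881. NOXO1 (780.3), GLT1D1 (736), MAPK4 (494), PRSS36 (368) and ST8SIA6 (322) followed. All had at most 1.97 CPM in armadillo and at most 0.727 in differentiated human cells. The 95% counting limits in armadillo reached 2.88 CPM for ESM1, 2.43 for TC2N and GLT1D1 and 2.24 for APOA1, and at a threshold of 1 CPM 5 of the 10 highest genes kept the pattern. Further members of the trophoblast and yolk sac list stood in opossum at 486 (AFP), 148 (APOA2) and 18.96 CPM (GCM1), and had 0 in differentiated human cells, whereas CYP19A1 (1.24) and PAPPA2 (0.448) were below 2.

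Abundant genes differed between the libraries. In differentiated human cells COL1A1 took 5.24% of the signal, COL1A2 2.65%, COL3A1 2.29%, IGFBP4 1.29% and SPARC 1.07%. In undifferentiated cells COL1A1 took 3.75%, COL1A2 2.17%, FN1 2.13%, THBS1 1.66% and COL6A3 1.36%. In armadillo FN1 took 2.21% of reads, EEF1A1 2.11%, the contractile genes TAGLN and MYH11 1.10% and 1.08%, VIM 1.02% and IGFBP2 0.923%. In opossum SOD3, an extracellular superoxide dismutase, took 6.60%, the retinol binding protein gene RBP4 2.17%, STC1 1.502%, FUCA2 1.05% and ARG1 1.05%. The 10 most abundant genes together held 12.1% of armadillo and 23.1% of opossum reads, against 14.2% to 15.7% of the human runs.

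Markers of cell types separated the libraries. All 12 matched stromal markers were at or above 2 CPM in both human libraries and armadillo, and 11 were in opossum. COL1A1 stood at 52410.2, 1895 and 127 CPM in differentiated human cells, armadillo and opossum, and MME was the 1 stromal marker higher in opossum than in armadillo, at 792 against 106. Of 7 matched epithelial and gland markers, 3 were at or above 2 in each human library and 6 in armadillo and in opossum. EPCAM stood at 7.72 CPM in armadillo and 191 in opossum, CDH1 at 6.81 and 133, and FOXA2, a gland transcription factor, at 1.29 and 163. Of 5 matched smooth muscle markers 4 were lower in opossum than in armadillo, MYH11 at 10803 CPM in armadillo and 108 in opossum and DES at 3160 and 127 among them, while ACTA2 stood at 161 and 317. Endothelial TEK stood at 430.5 in armadillo and 14.3 in opossum, and the leukocyte gene CD74 at 550.1 and 20.05. Of 9 leukocyte markers, 9 were at or above 2 in armadillo, 4 in opossum and 1 in differentiated human cells. All 3 matched endothelial markers were at or above 2 in armadillo and opossum, and 1 in differentiated human cells.

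**Figure D3:**
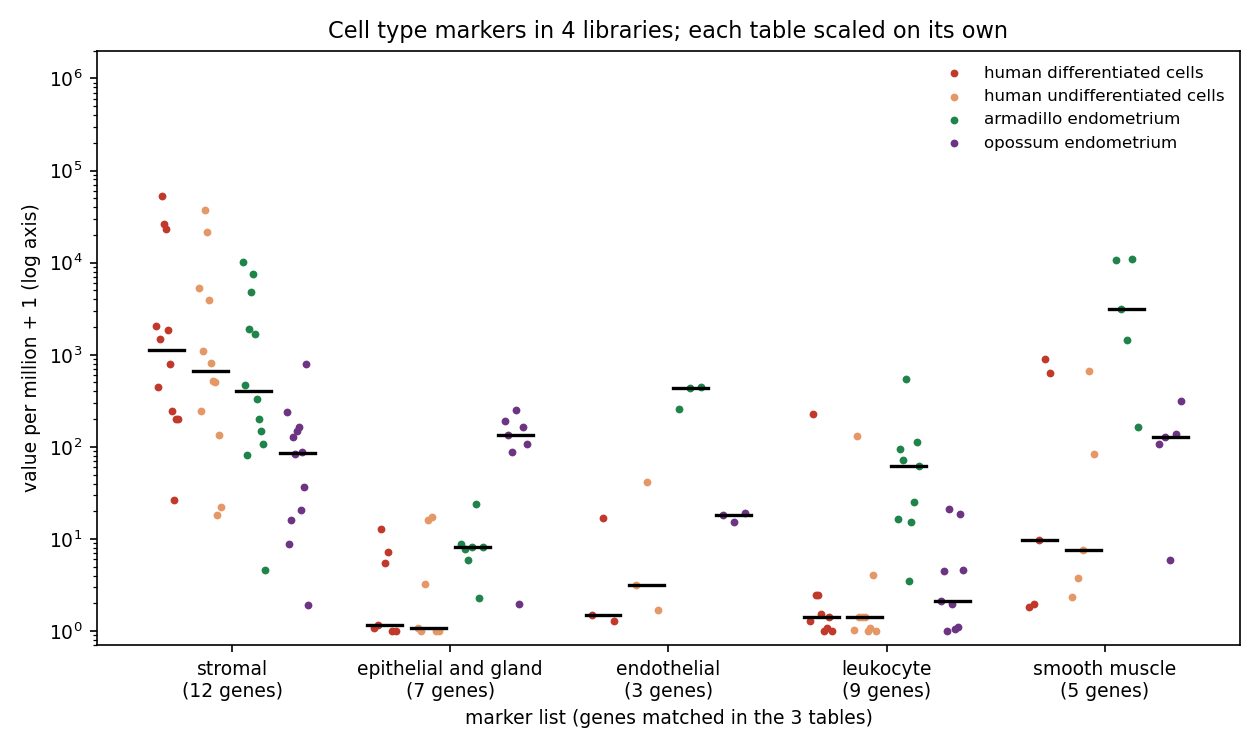
Values CPM with 1 added (vertical, log axis) of matched marker genes in 4 libraries, 1 point per gene, with the median of each list as a black bar. Each table was scaled on its own; the 7 epithelial markers have their highest median in opossum, and the 3 endothelial, 9 leukocyte and 5 smooth muscle markers in armadillo.

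The lists fixed in advance were also counted in each library, in the order differentiated human, undifferentiated human, armadillo and opossum. Of 15 matched decidual markers, 13, 9, 14 and 11 were at or above 2 CPM. STC1 stood at 41.7, 1454, 134 and 15018 CPM. Of 11 steroid-receptor targets, 11, 10, 11 and 10 were, with CEBPD at 57.5, 3.70, 36.3 and 867 CPM and CRISPLD2 at 1889, 10.6, 235 and 3.93. Of 11 genes that respond to cyclic AMP, 11, 10, 9 and 8 were. Cell cycle genes were at or above 2 for 18, 18, 17 and 10 of 18 members, and CENPF was at 89.0, 127, 24.7 and 1.19. In opossum 16 of these 18 were at or above 1 CPM, with BUB1 (1.04), CENPF, AURKA (1.39), FOXM1 (1.44), KIF11 (1.59) and BIRC5 (1.99) between 1 and 2. Endometrial transcription factors counted 13, 13, 13 and 11 of 14, with STAT3 at 279, 127, 349 and 126. For WNT and BMP genes the counts were 18, 17, 20 and 16 of 21, and FST, which binds activin, was at 163, 117, 133 and 1031. In the insulin-like growth factor axis they were 11, 9, 11 and 11 of 11, and IGFBP2 stood at 5.47, 0.146, 9230 and 47.9.

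Prostaglandin genes counted 6, 5, 10 and 8 of 10 matched members in the same order. The receptor gene PTGER4 stood at 12.1, 19.8, 20.4 and 2807 CPM, PTGS2, an inducible cyclooxygenase, at 0.0299, 0, 29.8 and 147, and HPGD, which degrades prostaglandins, at 0, 0, 2.04 and 353. Cytokine and chemokine genes counted 10, 13, 14 and 8 of 18, with IL1R1 at 510.1, 33.2, 121 and 8.56. Angiogenesis genes counted 11, 12, 16 and 14 of 16, with EPAS1 at 426, 124, 1237 and 200.5. Stress genes counted 12, 11, 12 and 12 of 12, and CAT, the catalase gene, was at 116, 51.6, 48.9 and 872. Matrix genes counted 21, 21, 21 and 20 of 21, proteases and inhibitors 9, 8, 8 and 7 of 9, and contractile genes 6, 7, 8 and 8 of 8. Immune tolerance genes counted 4, 4, 5 and 3 of 5, steroid receptors and enzymes 3, 2, 3 and 3 of 5, and sterol synthesis genes 7, 7, 7 and 6 of 7. All 3 interferon-response and all 8 ribosomal protein genes matched were at or above 2 in the 4 libraries. Smooth muscle markers counted 3, 4, 5 and 5 of 5, trophoblast and yolk sac markers 2, 2, 1 and 3 of 5, and erythroid markers 0, 0, 2 and 2 of 2.

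In all, 11410 genes were at or above 2 CPM in differentiated human cells, 11372 in undifferentiated cells, 10050 in armadillo and 11586 in opossum. Across the 8311 matched genes, which are not independent replicates, Spearman's rho was 0.946 between the human libraries. It was 0.666 between differentiated cells and armadillo, 0.576 between differentiated cells and opossum and 0.596 between armadillo and opossum. For undifferentiated cells it was 0.660 with armadillo and 0.573 with opossum. Species and gene annotation differed together between the human, armadillo and opossum tables, and cultured cells against tissue also differed between human and the others, so the values of rho do not separate these. With at least 5 CPM in the eutherian libraries and below 1 in opossum the count was 233 in place of 599, and 105 in place of 256 for the reverse.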

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

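The displacement test and both tests on cell type markers below were chosen only after the result was seen, as was the matched background of the test on ubiquitous complexes, whereas that test itself and the one on depth were set beforehand.

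Values on the X chromosome in the second differentiated run were used in no comparison, and they did not follow the first run of the same sample. Over 783 genes, Pearson r across genes was -0.0297 on log2 values, against 0.997 on chromosome 8 (698 genes) and 0.996 between the undifferentiated runs on X. The sorted values of the differentiated runs had an r of 0.990, so the values themselves were alike in range. With the second run moved by 13 genes along the chromosome r was 0.515, the highest of 30 displacements tried on each side, and at 12 genes it was 0.430, while on chromosome 8 r was highest at a displacement of 0. A candidate explanation is that values were assigned to neighbouring gene names in that column, which stays open, since no displacement brought r near that of the other runs.

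Reads on genes with no name of the human table entered no comparison. They made up 27.2% of opossum reads, on 9053 genes, and 12.2% of armadillo reads, on 1950 genes. The gene ENSMODG00000017141, singled out after its value was seen, held 7.67% of opossum reads (95% Wilson interval 7.66% to 7.68%). In armadillo ENSDNOG00000006719 held 1.09% and ENSDNOG00000008776 1.06%.

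Explanations were weighed for the 599 genes at or above 2 CPM in differentiated human cells and armadillo and below it in opossum. Loss of reads through opossum gene models or alignment stays open as a cause. Of 224 genes of ubiquitous complexes, 1 lay below 2 in opossum, or 0.446% (95% exact interval 0.0113% to 2.46%). Of genes matched on expression, 7.07% did. This cannot decide the question, since an abundant gene can lose most reads and stay above 2, and matching was on expression only. The ribosomal protein genes RPS6 and RPL8 stood at 1978 and 1985 CPM in armadillo against 16.9 and 70.5 in opossum. RPL5 was higher in opossum (609 against 430). Of the 599 genes, 28 had 0 opossum reads, among them AP2B1 (316 and 250 CPM in human and armadillo) and CYP51A1 (42.4 and 30.3), and YWHAQ had 5. Depth cannot be told apart for part of the pattern, since 74.8% of the genes (448) kept an upper 95% counting limit under 2 CPM and the others did not. Fewer stromal cells with other types unchanged would raise all other markers. Endothelial, leukocyte and smooth muscle medians of log2 opossum over armadillo were instead -4.53, -3.86 and -6.31, against -0.56 for all matched genes. ACTA2 was the 1 marker of these that was higher in opossum. The medians were therefore not raised relative to armadillo, but whether opossum held fewer stromal cells cannot be decided from them. A high level in armadillo lowers them too, and TAGLN and MYH11 were among its 10 most abundant genes. Of 5 matched smooth muscle markers, 3 were also at or above 2 in differentiated human cells. A larger share of epithelial cells in the opossum library could contribute, as epithelial markers had a median of 4.10 (6 of 7 higher in opossum, SPP1 the exception; KLF5 at 251 and EPCAM at 191 CPM the most abundant of these) and stromal markers -3.62 (MME the exception), while markers with a value in only 1 of these 2 tables were abundant on either side (KRT7 at 538 and KRT18 at 280.3 CPM in armadillo, WFDC2 at 1235 and KRT19 at 421 in opossum), 1 of the 20 epithelial markers listed is in another list and 3 of the 7 matched were at or above 2 in human stromal cells. Species differences stay open and untested, and trophoblast and yolk sac markers, of which APOA1 (881 CPM) and AFP (486 CPM) also stood high in opossum, were not part of these tests.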

How the results depend on the processing

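The settings with the first run alone, without X and unplaced genes, with both run pairs, with interval bounds, with opossum counting limits and with opossum reads per base were chosen after seeing the data. In human cells the 212 genes higher and 212 lower became 148 and 140 with a pseudocount of 5, 126 and 132 with a minimum of 50 CPM, and 617 and 845 with a 2-fold threshold. The last changes follow from construction, as fewer genes enter at 50 and more pass at 2-fold. Under the 9 other settings the counts ran from 193 to 263 higher and from 179 to 261 lower, and without the doubted second run they were 218 and 222. Upper-quartile scaling gave 258 higher and 179 lower, or 59.0% higher against 50%. With no minimum, where members near 0 enter, the cytokine list reversed to a median of -0.0827, and the medians of WNT and BMP (0.07), prostaglandin (0.05) and interferon genes (0.21) also turned positive.

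By the mean, 12 lists lay outside the random range in place of 15, with median-of-ratios scaling 15 and with the first run alone 14. With no minimum 15 of the same 22 lists did, and 17 of all 26, which then had enough members. The matrix list (percentile 98.1) and the interferon list (97.52) moved outside there, and the cytokine list (14.1) and epithelial markers (57.8) moved inside, the latter also with the first run alone (7.48). Of the 100 named human genes, none of those at least 4-fold apart changed sign under any scaling, pseudocount or the first run alone. For pseudocounts and scalings this was bound to hold. A pseudocount cannot change a sign, and the scalings moved log2 ratios by at most 0.17. Beyond the counting interval, 70 moved with a pseudocount of 5, 26 with 0.1, 64 with upper-quartile scaling, 41 with median-of-ratios scaling, 11 without the 20 most abundant genes and 11 with the first run alone.

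Across species, the 599 and 256 genes became 233 and 105 with at least 5 and below 1 CPM. Under the other settings they ran from 445 to 835 and from 203 to 315, with the highest count at a threshold of 5 and 813 with opossum reads per base. The 445 came from rescaling over matched genes. These held 52.4% of opossum reads, against 63.7% of the differentiated human signal and 68.4% of armadillo reads. With the first run alone, which leaves the armadillo and opossum values unchanged, 597 of the 599 genes were shared. At thresholds of 1 and 5 CPM 365 and 399 were shared, and 384 when rescaled over matched genes. With opossum reads per base 543 were. Over genes at or above 2 CPM in both libraries Spearman's rho was 0.896 between the human libraries, 0.567 and 0.443 for differentiated cells with armadillo and opossum, 0.575 and 0.445 for undifferentiated cells, and 0.443 between armadillo and opossum. The cause was not tested. Counts per library and list changed by over 1.5 times in 9 cases at thresholds of 1 and 5, among them cell cycle genes in opossum (16 in place of 10 at 1). The count by interval bounds was planned for read counts only. On human read equivalents, 208 genes had a bound at least 4-fold higher and 203 at least 4-fold lower, of which 206 and 200 were among the 212 and 212. Depth limits the low end, since 3 reads correspond to 0.149 CPM in opossum.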

Other observations

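The gene families in the next paragraph and their examples were chosen after the values were seen. The tests on the genes downstream of ERK were set before those genes were looked at, except for 3 genes that had drawn attention, and FOS, DUSP1 and JUNB were added after the result was seen.

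Integrin subunit genes stood lower in the differentiated library, with 8 of 15 at least 2-fold lower, none at least 2-fold higher and a median log2 ratio of -1.35 (-1.24 with median-of-ratios scaling). ITGA11, a collagen receptor subunit, stood at 26.9 against 425 CPM, a log2 ratio of -3.93, and ITGA3 at 17.8 against 173, a log2 ratio of -3.21. ITGA6 (0.53) and ITGAV (0.19) were on the other side of 0. Collagen chain genes went both ways, with 5 of 22 at least 2-fold higher and 5 at least 2-fold lower. COL15A1 (33.5 against 0.340 CPM) and COL14A1 (214 against 8.72) were higher, while COL13A1 (0.726 against 47.1) and COL12A1 (831 against 3151) were lower. The median of the collagen genes was -0.05, and it was 0.05 with median-of-ratios and 0.12 with upper-quartile scaling. In the HOXA cluster 4 of 6 genes were at least 2-fold higher, HOXA10, HOXA11, HOXA3 and HOXA5, whereas HOXA7 (-0.64) and HOXA9 (-0.37) were lower. In the HOXD cluster HOXD10 and HOXD11 were at least 2-fold higher and HOXD8 was at -0.66. The HOXB genes entering, HOXB2 (-0.88) and HOXB3 (-0.25), were lower.

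DUSP6, SPRY4 and ETV1, which are known to be induced by the ERK kinase pathway and, for DUSP6 and SPRY4, to restrain it, stood 57.6-fold (95% counting interval 42.2 to 80.9), 36.1-fold (30.6 to 42.7) and 36.7-fold (28.97 to 47.1) lower in the differentiated library. A list of 15 further genes known to follow that pathway was then written before their values were looked at, and of 13 entering 12 were at least 2-fold lower and none at least 2-fold higher, with a median log2 ratio of -2.11 (EGR1 at 10.4 against 253 CPM, SPRY2 at 16.2 against 112, CCND1 at 328 against 1423, but DUSP5 at 50.9 against 45.8). Of the listed genes below the minimum, SPRY1 was 1.88-fold higher (1.52 to 2.32), at 7.60 against 4.05 CPM. EGR2, also below it, was lower, at 0.0598 against 9.76 CPM. Other genes that respond early to the same pathway and to other signals went both ways, with FOS 2.71-fold higher (2.22 to 3.31), DUSP1, also a steroid-receptor target, 3.25-fold higher (3.12 to 3.39) and JUNB 3.35-fold lower (3.07 to 3.65). A shift of the whole library by scaling is argued against, since the median of the list lay at -1.97 relative to all genes. Lower output of the ERK pathway in differentiated cells is a candidate explanation, with the median at percentile 0 among matched random lists, whose central 95% ran from -0.54 to 0.24, but FOS and DUSP1 did not follow it, and serum and handling, to which many of these genes respond, were not tested.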
